A study of Caulobacter vibrioides with 6 samples.

How the data were processed

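The data were anti-FLAG ChIP-seq libraries of Caulobacter crescentus CB15N, a freshwater bacterium with a single circular chromosome. In ChIP-seq, proteins are crosslinked to DNA with formaldehyde, the DNA bound to one protein is pulled down with an antibody, and the recovered fragments are sequenced. There were 6 libraries in 6 groups, with 1 library per group, assigned from the sample titles and genotypes. Cells without a FLAG tag were sampled without and with zeocin (15 µg/mL), a drug that breaks DNA. Cells in which the transcription factor DriD carries a 3xFLAG tag were sampled without and with the same dose. A second strain with tagged DriD, a vanillate-inducible gene for the endonuclease I-SceI and an I-SceI site at CCNA_00727 was sampled without and with 0.5 mM vanillate. Per the labels, this strain also carries the didA promoter fused to lacZ at hfaB. No untagged library of that strain was analysed here, so the untagged libraries of the zeocin pair served as its background.

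Each deposited file lists the signal at every covered base, per the file headers a variable-step track on a chromosome named CB15N. The deposited signal is whole-number read depth (coverage), not scaled to library size, and bases without reads are left out. Bowtie2 and SAMtools are named in the submitters' processing notes, without versions. The assembly, the handling of duplicate reads and any read extension are not given in the sources used here. Listed positions count from 0 and were converted to 1-based coordinates, on a chromosome of 4042929 bp. Isolated stretches of depth 1 were 40 bp long in 98.3% to 99.1% of cases in every library, so the number of reads was taken as the summed depth divided by 40. Because the depth is unscaled, folds and ratios between libraries were taken after each was divided by its own background, and read counts and depths are given as they are.

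Gene names and neighbours came from the RefSeq gene table of assembly ASM2200v1 (4097 genes), whose coordinates are not printed because the files name no assembly. The table gives no symbol for CCNA_03212 and CCNA_01151; these were named didA and driD from general knowledge, after the files had been read. The tables used have no strand and no genome sequence came with the series. Promoter windows for the gene lists could therefore not be placed at start codons alone, and windows at both ends of each gene were used (300 bp outside to 100 bp inside). The planned search for a sequence shared by the regions was not run. Of the 169 gene symbols in the 12 lists fixed before the data were examined, 118 matched the table and 51 did not, including rpoB, gyrA, uvrA, ssb and most ribosomal protein genes.

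Depth was averaged in 50 bp bins and divided by the median of all bins within 10 kb on either side. The quotient is called enrichment (E), and it removes library size and the gradient from origin to terminus. An enriched bin had E of 3 or more and at least 2 times the higher E of the untagged libraries, with an untagged E under 1 taken as 1. Enriched bins up to 200 bp apart were merged, and a region spanned at least 100 bp. The response of a region was the ratio of its mean E with and without the treatment, over the union of the regions of the pair. A region was said to rise or fall when this fold was at least 1.5, or its inverse, and lay outside the central 99% of the same ratio over windows of equal width away from all regions and from the 2 ribosomal RNA operons. Regions of different libraries were shared when they overlapped by 1 bp or more. For the chromosome-scale comparisons the median depth of 10 kb bins was used, each library scaled to its own genome median. The origin was taken as the first base of the chromosome and the terminus as the point opposite. Intervals of the origin-to-opposite ratio came from 1000 resamples of 100 kb blocks, and those of the comparison within a pair from blocks drawn alike for both libraries.

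With 1 library per group there is no spread between replicates, and no p-value is given. Intervals beside folds are exact Clopper-Pearson 95% intervals of the read counts; they cover counting error only, and reads without molecular identifiers are not independent molecules. Positions of gene lists were described by the percentile of the list median among 10000 random lists of equal size matched on mean signal. Sequencing was shallow, from 611906 to 1321008 reads per library, with a median depth between 1 and 5.

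The rules were tested on simulated libraries only after they had first been applied to the real ones, and were not changed by the outcome. The simulated libraries shared one profile, taken from the pooled untagged libraries, and had the local background of each real library, over 80858 bins. In 5 simulations of unchanged libraries, the rule called on average 0.400 regions in the untreated tagged library of the zeocin pair, 7.20 in the zeocin library, 3 in the untreated I-SceI strain and 67.2 in the vanillate library. Of 50 sites of 200 bp planted at 5 times the background, 49 were found in the simulated zeocin library and 49 in the simulated vanillate library. At 10 times the background all 50 were found in each. At 3 times, 8 and 23 were found. The simulation draws reads independently and has no duplicates. For the untagged libraries over each other it gave 119 and 78.8 regions on average, fewer than the 797 and 214 of the real ones.

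Named genes followed a rule fixed at the same time as the lists, the tests and the alternatives. It takes the 10 regions with the highest ratio to the untagged signal in each tagged library, regions found in all 4 tagged libraries, and the 5 highest and 5 lowest folds among regions past the size rule of each response. It always takes didA, driD, recA, lexA, CCNA_00727, vanA, hfaB and the 16S ribosomal RNA gene, and from each gene list the members with the highest, the lowest or a region signal. Alternatives covered bin width, enrichment threshold, the untagged comparison, the background scale, the size rule, the measure of fold, the overlap rule, the bin size of the chromosome-scale values and the windows of the gene lists. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.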

Results

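Anti-FLAG ChIP-seq signal was compared between Caulobacter crescentus cells with and without a 3xFLAG tag on DriD, a transcription activator of the DNA damage response that acts independently of the SOS regulator LexA. Breaks were made either across the genome with zeocin or at 1 engineered place with I-SceI, an endonuclease with a long recognition site. The comparisons address where DriD is found on the chromosome and how this differs between cells with and without breaks. The untagged libraries held 844261 reads without zeocin and 1321008 with it. The tagged libraries of the zeocin pair held 1049630 and 799936 reads, and those of the I-SceI strain 874520 without and 611906 with vanillate. The share of bases without any read was 26.6% in the untreated untagged library and 28.9% in the vanillate library, against 2.29% to 18.2% in the others. Each value below rests on 1 library, so no difference could be set against a spread between replicates.

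Before the tagged strains were compared, the loci that differ between them by construction were examined. The strongest tag-dependent signal lay between didA, which encodes an inhibitor of cell division, and CCNA_03213, at 3375251 to 3375650. Its mean enrichment over the local background was 3.38 and 2.84 in the untagged libraries without and with zeocin, and 2.46 in the untreated tagged library of the zeocin pair. It was 23.7 with zeocin. In the I-SceI strain it was 8.83 without vanillate and 82.5 with it. In the untreated strains this region was thus 3.59-fold higher in the I-SceI strain (95% interval 2.87 to 4.52). A second site lay between CCNA_03891 and driD itself, at 1254601 to 1254800, with untagged values of 3.10 and 3.08. There the untreated tagged libraries had 5.2 (zeocin pair) and 5.09 (I-SceI strain), and the treated ones 17.9 with zeocin and 16.5 with vanillate. The ratio of the untreated strains at driD was 0.979 (0.772 to 1.2).

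**Figure D1:**
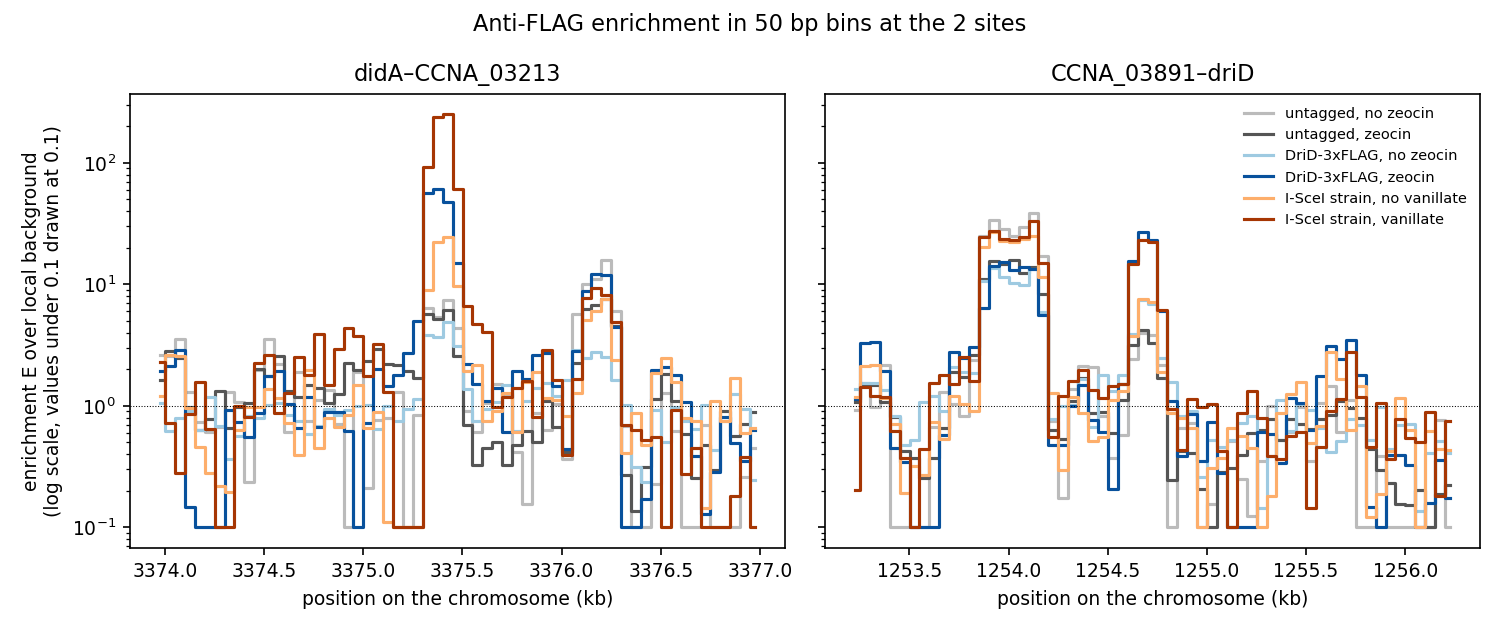
Enrichment over the local background in 50 bp bins (log axis) against chromosome position in kb, over 3 kb around the didA (left) and driD (right) sites, with one line per library and values under 0.1 drawn at 0.1. Within the didA site the highest bin reached 252 with vanillate and 60.9 with zeocin, against 7.47 and 6.11 in the untagged libraries without and with zeocin; within the driD site the highest bins were 23.0, 26.8, 3.96 and 4.19. Beside the didA site the untagged libraries reach 15.9 and 7.51, at 3376201 to 3376250. The tallest peak near driD, at 1254101 to 1254150, does not need the tag: 39.0 in the untreated untagged library and 33.4 with vanillate.

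The other engineered loci with a region were highest in the I-SceI strain. Between vanR and vanA, the regulator and an enzyme gene of vanillate metabolism where the I-SceI gene was placed, the highest bin of the region at 2620551 to 2621000 was 44.5 without and 111 with vanillate. The summit bin held 8.42 and 6.49 in the untagged libraries, and 3.92 and 12.1 in the tagged libraries without and with zeocin. Between CCNA_02473 and CCNA_02474, next to this locus, the summit reached 14.2 and 23.2, against 0.462 to 1.3 in the other 4 libraries. In hfaB, a holdfast attachment gene that carries the didA promoter fusion, a region at 2871301 to 2871400 had a summit of 6.01 without and 10.3 with vanillate, and at most 1.24 elsewhere. The vanR to vanA and hfaB loci carry inserted sequence in this strain only, so the untagged libraries are no matched background there. The same may hold for the space between CCNA_02473 and CCNA_02474, which was not examined for inserted sequence. Over CCNA_00727, which holds the I-SceI site, depth was 3.79 without and 0.394 with vanillate, that is 56.5 and 5.88 reads, in libraries of unequal depth. Divided by the local background, the fold was 0.461 (0.183 to 1.04), which includes no change relative to the surroundings. The surroundings were themselves lower with vanillate: scaled to the genome median, the depth ratio within 50 kb was 0.505. The fold over the local background leaves this wider decrease out. Over 188 bp of the didA coding sequence, at 3375123 to 3375310, both libraries of the I-SceI strain held 0 reads. The zeocin libraries held 46.7 reads there without the tag and 40.6 with it, and the untreated libraries 3.85 and 21.1.

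The 16S ribosomal RNA genes were strongly enriched in every library, tagged or not. Enrichment over the copy CCNA_R0087 was 267 in the untreated untagged library, 41.9 in the untagged zeocin library and 26.9 to 164 in the tagged libraries. The 2 ribosomal RNA operons took 40.6% of all signal in the untreated untagged library and between 9.64% and 29.0% in the others.

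The number of enriched regions differed widely between the tagged libraries. The untreated library of the zeocin pair had 1 region, inside rsaA, the surface layer protein gene (1161851 to 1162000, 2.52 times the untagged signal). With zeocin there were 394 regions. The I-SceI strain had 12 regions without vanillate and 283 with it. The regions were mostly weak: the median ratio to the higher untagged signal was 2.70 with zeocin and 2.97 with vanillate, and 12 regions in each of these libraries exceeded 5 times. Summits fell between genes in 18.8% of the zeocin regions and 13.4% of the vanillate regions, against 8.90% of the chromosome. The rule also called regions where there was no tag. The untreated untagged library gave 797 regions over the untagged zeocin library, and the reverse comparison gave 214. Each of these used 1 control, not the higher of both untagged libraries as for 394 and 283. Over the same single controls the tagged zeocin library gave 979 and 1071, in that order, and counts of the other tagged libraries are given below. Over the tagged zeocin pair the untagged libraries gave 377 and 10. In simulated unchanged libraries the rule called on average 7.20 regions in the zeocin library and 67.2 in the vanillate library. The same simulations gave 119 and 78.8 regions for the untagged libraries over each other, where the real ones gave 797 and 214. They thus understated calls without a tag, and their counts are no measure of false calls in the real libraries. Both controls and the scale set the counts of the tagged libraries. In the order untreated, zeocin, untreated I-SceI strain and vanillate, they were 1, 28, 4 and 9 with total signal as scale. They were 10, 979, 101 and 921 without the untreated untagged library, and 6, 1071, 106 and 665 without the untagged zeocin library. Total signal as scale divides by the mean depth, 7.91 with zeocin and 6.05 with vanillate. The median local background was 2.66 and 1.38, so E of 3 is a higher bar on that scale by construction.

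In the zeocin library the region at didA led the ranking with 11.3 times the higher untagged signal and 480 reads. It was followed by the space between CCNA_01732 and CCNA_01733 (6.87 times), a region inside CCNA_00940 (6.48 times), the driD site (6.40 times) and the space between CCNA_01449 and recJ, a gene for a single-strand exonuclease (6.22 times). Around the ends of recJ as a whole, signal did not need the tag. Mean E there was 29.1 and 5.98 in the untagged libraries without and with zeocin, and 7.12 in the tagged zeocin library. Regions inside ftsW, a cell division gene, CCNA_02895, CCNA_01773, the efflux gene acrB4 and CCNA_02979 had ratios from 6.17 down to 5.02, with 19.8 to 49.1 reads each. In the vanillate library the ratio at didA was 44.4 with 1182 reads, followed by the CCNA_02473 (18.5), vanR (13.2) and hfaB (8.36) sites named above. Next came regions inside tipF (7.29), sgt1 (6.45), CCNA_01036 (6.35), the inositol catabolism gene iolD (5.81), driD (5.78) and CCNA_00580 (5.51). Of these, driD held 187 reads and the others between 6.90 and 35.5. Without vanillate, the highest ratios were at CCNA_02473 (11.3), vanR (5.29), CCNA_02602 (4.52) and didA (4.18). Regions inside CCNA_00095, CCNA_02474, CCNA_00490, CCNA_01163, iolA and CCNA_03740 had ratios between 3.06 and 2.28. Under a stricter rule chosen after the data were seen (E of 10 or more and 4 times the untagged signal), the counts in the same order were 0, 4, 2 and 4. In the zeocin library these were didA, driD, the space between CCNA_01732 and CCNA_01733, and bapE, a LexA-controlled endonuclease gene. In the vanillate library they were didA, driD, vanR and CCNA_02473.

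The zeocin response was measured over 395 regions. Of these, 64 rose past the size rule and 0 fell, where a fall was hardly possible because most regions were called for a high zeocin library. The number that rose was 9 with total signal as scale, 3 by the ratio of E minus 1 and 12 with bins of 200 bp. The didA region rose 11.1-fold (9.0 to 14.1), from 97.2 to 480 reads, while the same stretch in the untagged libraries had a fold of 0.867. The other 4 of the 5 highest folds, at CCNA_00830 (12.0-fold), the space between CCNA_03147 and CCNA_03148 (11.1-fold), CCNA_01105 (10.5-fold) and the space between CCNA_02994 and CCNA_02995 (10.2-fold), rested on 3.98 to 7.08 reads without zeocin. Among well-covered regions, bapE rose 9.32-fold (6.49 to 13.6; 223 reads with zeocin), CCNA_01732 to CCNA_01733 rose 9.45-fold (5.62 to 16.8) and CCNA_01449 to recJ rose 4.72-fold (3.32 to 6.77). Over the whole bapE gene the zeocin fold was 2.91 (2.26 to 3.81) and the vanillate fold 1.07 (0.608 to 1.75). The lowest folds among those that rose were at CCNA_03151 (4.10), CCNA_01925 (3.95), CCNA_02487 (3.91), CCNA_01909 (3.67) and zrpX (3.66). The driD region had a fold of 3.43 (2.89 to 4.11), which lay inside the central range of equal windows off all regions, whose upper end was 4.11. It did pass under the other scales, in a comparison chosen after the data were seen: 5.52 against 4.17 with the genome-wide median, 5.06 against 4.09 with the background within 50 kb, and 3.96 against 3.04 with total signal. Windows off all regions hold far fewer reads: the median local background with zeocin was a depth of 2.66, against 105 at driD. Counting error widens the range of such windows, so a place inside it does not show that driD was unchanged. Part of the fold may not be particular to driD, whose mean E in the untagged libraries was 3.10 and 3.08. Over single bins with E of 3 or more in both untagged libraries, the median zeocin fold of the tagged pair was 2.20 (quartiles 1.62 and 2.91). The median fold over all 395 regions was 3.15, against 1.2 in the untagged pair. Most of these regions were called because the zeocin library was high, so a fold above 1 follows in part from the selection. In simulated unchanged libraries the median was 2.07. There 0 regions rose, but out of only 7.20 on average, and all simulated libraries shared the same profile. This 0 therefore says little about the 64 regions that rose. Over 15643 bins picked only because both untagged libraries had E of 2 or more, the median fold was 2.14 in the tagged pair (quartiles 1.56 and 2.87) and 0.752 in the untagged pair. For recA and lexA, the recombinase and repressor genes of the SOS response, the zeocin folds over the gene were 2.29 (1.98 to 2.61) and 2.11 (1.73 to 2.68).

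The vanillate response was measured over 291 regions. The size rule was passed by 17 that rose and 0 that fell, with the same limit on falls. It was passed upward by 2 with total signal, 6 by E minus 1 and 3 with bins of 200 bp. The didA region rose 9.35-fold (8.04 to 10.6), from 259 to 1182 reads. The 5 highest folds were at CCNA_01018, sdpA, sgt1, CCNA_01036 and CCNA_02802. These rested on 0.450 to 3.20 reads without vanillate, and their intervals began at 2.60 to 4.57. CCNA_02782 rose 7.86-fold (5.84 to 10.9), from 51.0 to 261 reads; it lies outside the naming rule and was chosen after its values were seen. The lowest folds among those that rose were at CCNA_02797 (5.0), CCNA_02310 (4.54), CCNA_00725 (4.24), CCNA_02834 (4.19) and CCNA_00660 (3.06). The driD region had a fold of 3.25 (2.56 to 4.11), inside the central range that ended at 4.42 and inside those of the other scales, and the vanR region had 2.32 (2.07 to 2.61), inside a range that ended at 2.89. Counting error widens these ranges too: the median local background with vanillate was a depth of 1.38, against 37.4 at driD. The median fold was 2.51 over all regions and 2.02 in simulated unchanged libraries. Over the gene spans, recA had a vanillate fold of 2.24 (1.86 to 2.72) and lexA of 2.13 (1.73 to 2.66). Over the bins with E of 2 or more in both untagged libraries, the median was 1.44. With E of 3 or more, as at driD on average, it was 1.52 (quartiles 1.16 and 1.91).

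Of the zeocin regions, 47 overlapped a vanillate region. Shifting the regions along the chromosome gave 8.24 overlaps on average and at most 21 in 10000 shifts. Simulated unchanged libraries with the same controls shared 1 of 7.20 zeocin regions on average, a share no lower than 47 of 394 but from few regions. The shifts ignore the shared controls, so these may account for some or all of the excess over the shifts. The simulations cannot tell how much, since they shared at most 2 regions. The union held 637 regions: 50 lay in 2 or more libraries, 2 in 3, and 0 in all 4. At 38 of the 47 shared regions both folds were 1.5 or more, and at 5 both were 3 or more. High folds follow in part from the selection, since both libraries with breaks were high there, and in simulated unchanged libraries the median folds at called regions were 2.07 and 2.02. The 5 were didA (9.66 with zeocin and 9.35 with vanillate over the joint region), driD (3.43 and 3.25), the hook-filament junction gene flgL (4.32 and 3.54), CCNA_02782 (4.27 and 7.86) and CCNA_02537 (3.37 and 3.15); flgL, CCNA_02782 and CCNA_02537 were named after their values were seen. The stricter rule left didA and driD as the shared regions. Across 631 regions of the union with reads in every library, log2 folds of the pairs had r = -0.336 and rho = -0.362, and r turned to 0.322 with total signal as scale. Each region of the union was mostly called in 1 of the treated libraries, and unchanged simulated libraries gave a mean r of -0.189. Over the 50 regions of 2 or more libraries, r was 0.491 and rho 0.382. Regions are not independent replicates. At regions chosen in the I-SceI strain, the zeocin fold had a median of 1.90 and was above 1 at 254 of 291; at regions chosen in the zeocin pair, the vanillate fold had a median of 1.2 and was above 1 at 253 of 395. The untagged zeocin fold leaned the same way, with a median of 1.2 and 281 of 395 above 1 at the regions of the zeocin pair, and 1.14 and 179 of 291 at those of the I-SceI strain.

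**Figure D2:**
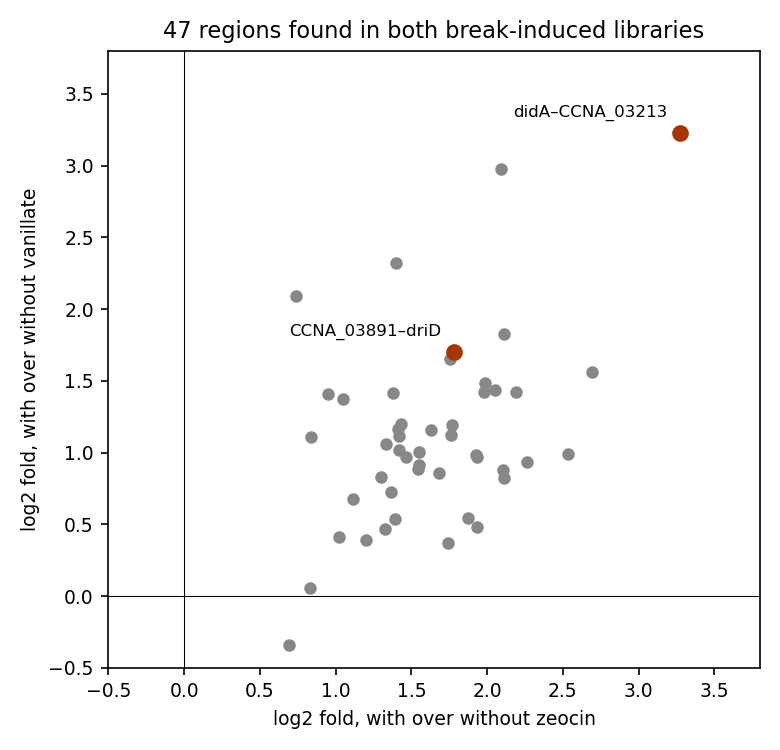
The log2 fold with over without zeocin against the log2 fold with over without vanillate for the 47 regions found in both libraries with breaks, 1 point per region. The didA site lies at 3.27 and 3.22, and the driD site at 1.78 and 1.70.

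Depth around the I-SceI site was lower with vanillate. Median depth within 200 kb of CCNA_00727, with over without vanillate, was 0.619 (0.566 to 0.668 over resampled bins), and 0.505 within 50 kb. The bin that holds the site had 0.472. The median of the 2 bins within 10 kb was 0.705, because the other bin, at 770001 to 780000, had 0.938. In that other bin the zeocin pair had 1.72. Beyond 500 kb the ratio with over without vanillate was 1.02, with 95% of bins between 0.732 and 1.36. All 20 of the lowest 10 kb bins lay within 500 kb of the site. The smoothed ratio stayed under 0.8 from 620001 to 1170000, which is 163 kb to the left of the site and 387 kb to the right. In the zeocin pair the ratio within 50 kb was 0.986. Of the vanillate regions, 109 (38.5%) lay within 500 kb of the site, a stretch with 24.8% of all bins; of the zeocin regions, 86 (21.8%) did.

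**Figure D3:**
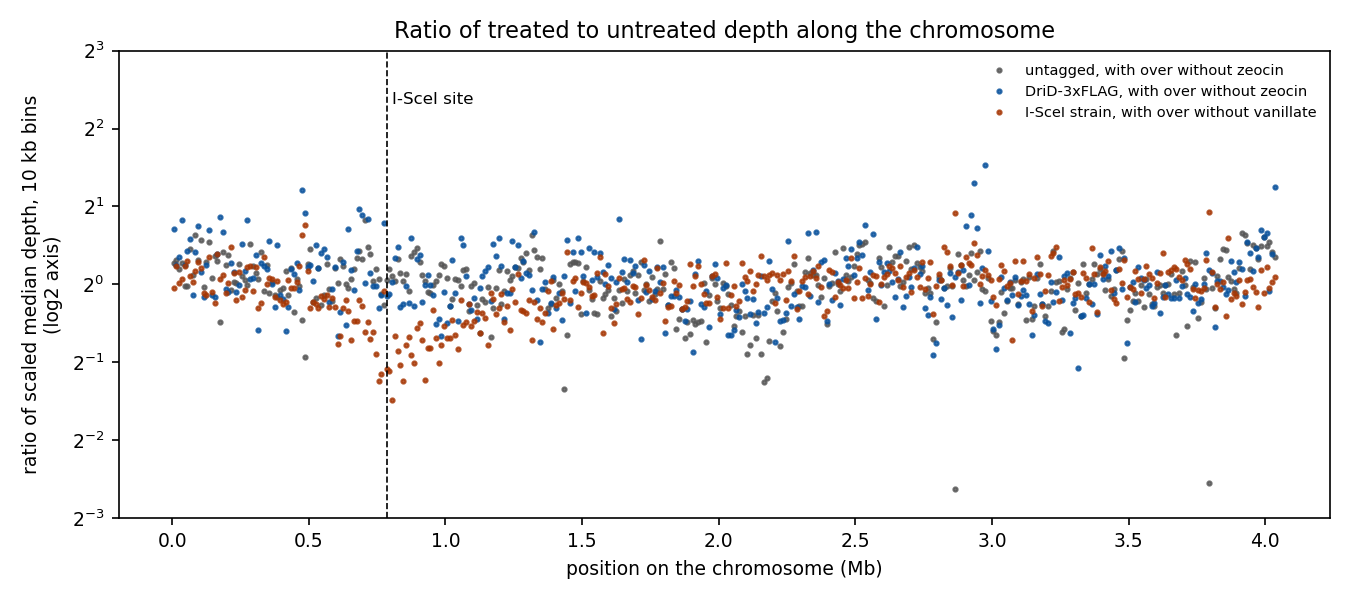
Ratio of scaled median depth in 10 kb bins (log2 axis) against chromosome position in Mb, for the untagged zeocin pair, the tagged zeocin pair and the I-SceI strain with over without vanillate; the dashed line marks the bin with the I-SceI site. Within 50 kb of the site the median ratio was 0.505 in the vanillate pair and 0.986 in the tagged zeocin pair.

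Background depth fell from the origin to the opposite point of the chromosome in all libraries. The ratio was 1.51 (1.22 to 1.86) and 1.93 (1.62 to 2.22) in the untagged libraries without and with zeocin, and 1.5 (1.35 to 1.70) and 1.84 (1.49 to 2.19) in the tagged ones. In the I-SceI strain it was 1.52 (1.34 to 1.75) without and 1.57 (1.27 to 1.94) with vanillate. With both libraries of a pair resampled over the same blocks, a comparison added after the data were seen, the ratio of these ratios (with over without) was 1.22 (1.05 to 1.39) in the tagged zeocin pair and 1.28 (1.06 to 1.51) in the untagged pair. It was 1.03 (0.898 to 1.14) in the vanillate pair. The intervals cover variation along the chromosome and not between cultures, with 1 library per group.

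Ratios of gene list members are given for whichever library with breaks was higher, unless named. Of all genes, 15.1% had a zeocin region inside or within 300 bp, and 11.1% a vanillate region. Member counts of the lists are to be read beside these shares, and no list was tested for an excess of members with a region. Around the ends of didA the signal was 4.93 times the untagged level with zeocin and 16.7 times with vanillate, and around driD 4.17 and 3.89 times. In the SOS regulon, 2 of 12 matched members had a zeocin region (bapE and dnaE2) and 3 a vanillate region (recA, sidA and dinB). The highest ratios were 1.91 at bapE with zeocin and 1.84 at recA with vanillate, and the lowest 0.528 at ruvB. The list median lay at the 84.1st percentile of random lists with zeocin and the 95.3rd with vanillate. These depended on the scale: against the genome-wide median they were 7.88 and 99.6, with the background within 50 kb the vanillate value was 98.0, and with total signal it was 33.9. In DNA repair and recombination, 3 of 11 had a zeocin region (uvrD, addA and recJ) and 2 a vanillate region (uvrD and addA), with the highest ratios at recF (1.47) and recR (1.46), the lowest at recJ (0.533) and the list at the 63.7th and 72.2nd percentiles. Of 18 cell division genes, 4 had a zeocin region (didA, kidO, ftsW and ftsZ) and 3 a vanillate region (didA, sidA and gdhZ); kidO had a ratio of 1.92 with zeocin and ftsE the lowest value at 0.624. That list lay at the 68.8th and 33.5th percentiles. The cell cycle list had 0 and 2 of 18 members with a region (tipN and pleC, with ratios of 1.39 and 1.15; ctrA was lowest at 0.605) and lay at the 6.98th and 19.2nd percentiles. With zeocin that list reached 1.51 with total signal and 2.07 over whole gene bodies, and with vanillate 1.16 with windows of 100 bp.

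The replication list had 1 of 6 members with a zeocin region (dnaG, 1.39) and 1 with a vanillate region (dnaE, 1.73), with dnaX lowest at 0.955, and lay at the 94.0th and 36.9th percentiles. Topoisomerase and nucleoid genes had 0 regions in 8 members, with the highest ratios at gyrB (1.42) and smc (1.38), the lowest at ihfA (0.934), and percentiles of 92.3 and 67.7. Of 19 flagellum and pilus genes, fliM had a zeocin region, fliQ had a region without vanillate, and fljL, fliN, flbD, flgE and fliF had a vanillate region. The highest ratios of that list were at fliP (1.48) and flgI (1.41) and the lowest at fliX (0.810), with percentiles of 46.3 and 76.0. Of 10 heat shock and proteolysis genes, grpE, dnaK and rpoD had a zeocin region and clpA a vanillate region; grpE had 1.75, dnaJ 1.45 and clpP 0.717, and the list lay at the 82.4th and 71.9th percentiles. The 4 oxidative stress genes had 0 regions, with ahpF at 1.68, katG at 1.14 and oxyR at 0.579, and percentiles of 50.6 and 39.2. The 6 matched highly transcribed genes (dnaK 1.37, rpsJ 1.12, rplB 0.784) lay at the 2.12th percentile with zeocin and the 80.1st with vanillate, and the last fell to 0.130 against the genome-wide background, 0 with the background within 50 kb and 19.8 with total signal. The engineered loci lay at the 97.6th percentile with zeocin, which fell to between 33.7 and 86.7 under the other 5 settings tried, and at the 22.0th with vanillate (3.79 to 95.3 under the same settings); vanB had a vanillate region at a ratio of 1.27 and hfaA the lowest value at 0.826.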

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

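The tests of contrast at places that stand out without the tag, of the share of regions near the I-SceI site, of a second didA promoter copy and of precipitation yield were chosen only after the results were seen; the tests by thinning and of I-SceI activity without vanillate were set before their results were seen. The zeocin fold was above 1 in the tagged strain and under 1 in the untagged strain at 3 of the loci always examined, but all 3 untagged counting intervals include no change, and the differences were not tested, with 1 library per group. At the didA region the fold was 9.66 with the tag and 0.839 (0.588 to 1.2) without it. At the driD region it was 3.43 and 0.994 (0.695 to 1.5). Over lexA it was 2.11 and 0.835 (0.668 to 1.05). Both lay closer to 1 than the medians of 2.14 and 0.752 over all bins with E of 2 or more in both untagged libraries. Over recA both were above 1, at 2.29 and 1.24 (1.05 to 1.47).

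The tagged libraries from cultures with breaks had 394 (zeocin) and 283 (vanillate) regions, and their untreated partners 1 and 12. Thinning the untreated tagged library to the local background of the zeocin library gave 2.08% of the zeocin regions. Lower depth with the profile of the untreated library thus did not give such counts. That library had the lowest E of the 6 at places that stand out without the tag, as given below. The thinning therefore cannot tell what lower depth adds in a library with stronger contrast. The same for the vanillate library gave 30.3%, so depth may account for a part and the rest is undecided. Over bins picked only because both untagged libraries had E of 2 or more, the median zeocin fold of the tagged strain was 2.14. Median E over these bins was 2.54 in the untreated tagged library, the lowest of the 6 libraries, and 5.70 with zeocin. It was 5.08 and 4.01 in the untagged libraries without and with zeocin. Regions were called against the untagged libraries, so this fold alone does not show why 394 were called. Different contrast at places that stand out without any tag stays a candidate explanation for part of the difference in counts. The corresponding vanillate fold was 1.44, between the bounds set for and against this explanation. DriD binding at many places after breaks remains open and was not tested apart from these explanations.

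The regions of the vanillate library gathered around the I-SceI site, with 109 of 283 within 500 kb. Thinning the untreated library of that strain to the lower local background gave 26.6 regions there on average, 24.4% of those in the vanillate library. Libraries simulated without any change gave 30.6. As a share of all regions, 38.5% lay within 500 kb in the vanillate library, 31% after thinning and 45.5% in the simulation, so lower local depth may account for the gathering as a share, while the number of regions there stays undecided. Binding of DriD near the break was not tested separately from the lower depth there.

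The didA signal of the untreated I-SceI strain was 3.59-fold that of the untreated strain of the zeocin pair, and 2.70-fold with total signal as scale. Over 2272 windows of 400 bp with E of 2 or more in both untagged libraries, that ratio had a median of 1.44 and a central 95% from 0.869 to 2.20. The didA ratio is 1.63 times the upper end of this range, and against windows of equal width 1.87 times without the bins that lack reads and 1.93 times over the region called in the untreated I-SceI library; these are near but under the bound of 2 set against a second copy of the didA promoter, which may contribute and stays open. A higher yield of the precipitation also stays open. At driD, the only other site of the stricter rule in both libraries with breaks, the ratio was 0.979 over the whole site. It was 1.01 over the part that passed the stricter rule, and this site alone decides nothing. The ratio was 1.53 over lexA and 1.37 and 1.44 over the 16S genes. These genes were also enriched in the untagged libraries, so their ratios do not measure the yield for tagged DriD. I-SceI activity without vanillate stays open too. The ratio of the untreated libraries within 50 kb of the site was 0.961, inside the range of 0.830 to 1.2 of distant bins. Activity in a small share of cells would move this ratio little, so it cannot decide. The driD site, with a vanillate fold of 3.25, was not higher in the untreated I-SceI strain, as given above. At didA the ratio of the strains with breaks, vanillate over zeocin, was 3.47 (3.11 to 3.85), against 3.59 without breaks. These values rest on 1 library per group and on single sites.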

How the results depend on the processing

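Depth limited the vanillate library: with a median depth of 1, a typical region held 19.0 reads, against 42.6 in the zeocin library. Of 263 values of the main results under other settings, 131 stayed within the margin set for them, 130 moved and 2 reversed; of 131 values for single lists and medians, 118 stayed, 13 moved and 0 reversed. No paired analysis was possible because the labels give the groups no shared replicate numbers. The search for a shared sequence and its 2 alternatives were not run, without a genome. The strict threshold, the settings that leave out 500 kb on either side of the I-SceI site those that leave out an untagged library, and the comparison of origin-to-opposite ratios within pairs with its settings were chosen after seeing the data. The origin-to-opposite ratios and their ratios within pairs stayed within their margins under every setting run. The cause of the changes was not tested, except that a stricter threshold leaves fewer enriched bins by construction. Total signal as scale also raises the depth that a given E requires.

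Region counts below are in the order tagged untreated, tagged zeocin, I-SceI strain untreated and I-SceI strain with vanillate, where 1, 394, 12 and 283 were reported. They were 0, 617, 29 and 594 with bins of 20 bp, 1, 470, 27 and 331 with bins of 100 bp, and 0, 81, 6 and 78 with bins of 200 bp. At E of 2 or more they were 10, 609, 61 and 575, and at E of 5 or more 0, 186, 5 and 105. At 1.5 times the untagged E they were 4, 1249, 72 and 779, at 4 times 0, 10, 2 and 6, and with no untagged comparison 1083, 2792, 1849 and 2340. The matched untagged library only gave 6 and 979 in the zeocin pair, and the mean of the untagged libraries 2, 864, 46 and 551. The genome-wide median as background gave 2, 324, 7 and 242, and total signal of the library as scale 1, 28, 4 and 9. At E of 10 or more and 4 times the untagged E they were 0, 4, 2 and 4, and without 500 kb on either side of the I-SceI site 0, 308, 9 and 174. They were 10, 979, 101 and 921 without the untagged library without zeocin, and 6, 1071, 106 and 665 without the untagged library with zeocin.

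The untagged counts (untreated over zeocin, zeocin over untreated, then each over the tagged zeocin pair) were reported as 797, 214, 377 and 10. They were 1386, 315, 694 and 23 with bins of 20 bp, 869, 240, 488 and 23 with 100 bp, and 440, 39, 265 and 0 with 200 bp. At E of 2 or more they were 1241, 597, 659 and 47, and at E of 5 or more 521, 27, 265 and 1. At 1.5 times the control they were 1397, 428, 747 and 57, at 4 times 41, 8, 10 and 0, and with no comparison 2169, 2081, 2169 and 2081. The genome-wide median gave 749, 246, 388 and 5, total signal 10, 222, 8 and 0, and the local background within 50 kb 782, 202, 368 and 4.

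The zeocin and vanillate libraries shared 117 regions with bins of 20 bp, 7 with 200 bp, 88 at E of 2 or more, 21 at E of 5 or more, 315 at 1.5 times and 2 at 4 times the untagged E, against 47 as reported. They shared 2089 with no untagged comparison, 2 at E of 10 or more and 4 times the untagged E, 27 by reciprocal overlap of 50%, 274 without the untagged library without zeocin and 338 without the one with zeocin. Regions in all 4 tagged libraries, 0 as reported, numbered 1 at E of 2 or more, 1 at 1.5 times, 948 with no untagged comparison and 2 without the untagged library without zeocin.

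Regions that rose with zeocin, 64 as reported, numbered 12 with bins of 200 bp, 41 with the genome-wide median, 9 with total signal and 3 by the ratio of E minus 1. With vanillate, 17 as reported, they numbered 34 with bins of 20 bp, 3 with 200 bp, 2 with total signal, 9 with the background within 50 kb, 6 by the ratio of E minus 1 and 8 without 500 kb on either side of the site. The didA zeocin fold was 7.74 with bins of 100 bp, 6.39 with 200 bp, 7.81 with the genome-wide median, 5.61 with total signal, 15.6 by E minus 1 and 12.5 by summit height. The didA vanillate fold was 6.90 with bins of 200 bp and 6.53 with total signal. The driD zeocin fold was 5.52 with the genome-wide median and 5.06 with the background within 50 kb, and its vanillate fold 2.27 with total signal. The ratio of the untreated strains at didA was 2.70 with total signal. The correlation of log2 folds over regions turned from -0.336 to 0.322 with total signal and to 0.491 over regions found in 2 or more libraries, and was -0.161 by E minus 1. The ratio within 200 kb of the I-SceI site was 0.546 after division by the zeocin pair. Lists outside the central 95% of random lists, 2 with zeocin and 0 with vanillate as reported, numbered 1 and 2 with the genome-wide median, 1 and 2 with the background within 50 kb, and 1 and 1 with windows of 100 bp.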

Other observations

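The test in the last paragraph was chosen only after the result was seen. Enrichment at the 16S ribosomal RNA genes differed between libraries with and without the tag alike. Over CCNA_R0069 it was 526 without and 70.3 with zeocin in the untagged strain, and 113 and 47.3 in the tagged strain. In the I-SceI strain it was 155 without and 222 with vanillate. The zeocin folds were 0.134 (untagged) and 0.418 (tagged), and the vanillate fold was 1.43.

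Of the zeocin regions, 216 (54.8%) lay where both untagged libraries had E of 1.5 or more, and of the vanillate regions 128 (45.2%), against 26.0% of all bins. Counted as genes with a region inside or within 300 bp, the zeocin library reached 617 and the vanillate library 454 of 4097 genes.

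Both libraries of the I-SceI strain held 0 reads over 188 bp inside didA, at 3375123 to 3375310, next to the strongest peak of the series. Mean depth there was 0.819 and 9.93 in the untagged libraries without and with zeocin, and 4.49 and 8.63 in the tagged ones; the untreated untagged library held only 3.85 reads. Of 4440 other windows of that length covered as deeply in the untagged zeocin library and both tagged libraries of the zeocin pair, 0 were without reads in the untreated I-SceI library, and 0 in the vanillate library. Stretches this long without reads were not rare without regard to coverage, 13 in the untreated and 648 in the vanillate library, and shifting one library against the other gave 0.189 joint ones on average and up to 3 in 1000 shifts, against 1 found. A hypothesis is the absence of that part of didA from the genome of the I-SceI strain, which may account for these 0 reads; the labels used here state no such deletion. The gap was noticed and tested on the same libraries.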
